A study of Homo sapiens with 18 samples.

How the data were processed

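RNA of 451 Lu melanoma cells was measured on 18 Affymetrix HuGene-2.0-ST arrays, 12 in the mimic arm and 6 in the inhibitor arm. The groups, taken from the sample titles, were control mimic input, control mimic pull-down, miR-340 mimic input, miR-340 mimic pull-down, control inhibitor and miR-340 inhibitor, with 3 arrays each. Per the labels' protocols, inhibitor and control hairpin vectors carried a fluorescent marker and positive cells were sorted 24 h after transfection, so genes were measured in transfected cells of that arm only. Per the file headers, the authors made log2 expression values with RMA in Affymetrix Expression Console, one value per transcript cluster, with the na35 annotation on genome build hg19. RMA corrects background, normalizes arrays to a common distribution and summarises probes, so a change shared by most RNAs of a fraction is removed by it. Per the submitters' processing notes, affy, RMA and limma were used, with versions not given in the sources used here. Whether both arms were normalized in 1 run is also not given, and no value was compared between the arms by a test. The deposited workbooks also give a score for each cluster and comparison, a signed fold change in which a ratio below 1 is written as minus its inverse. Each p-value and false discovery rate in the workbooks was computed by the authors with moderated statistics, per the file headers. These deposited scores and p-values were used to describe the authors' selections and counts, not for the tests here. They come from the same arrays and the same kind of test. With all clusters tested singly, the fit here called as many as the authors for pull-down against input, 9126 and 8935. The authors' counts are therefore no independent support for those given here.

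The series value table, with 53617 clusters, was the main source. The workbooks list 44629 of them, and their values differed from it by at most 5.0e-05. In the workbooks 25298 clusters hold 1 gene ID, 2427 several and 16904 none; clusters with several or none, BRAF's among them, were not named. IDs were matched to the RefSeq gene table of assembly GRCh38.p14, used for names only because the array annotation is on another build, and no coordinates are given. Of the clusters with 1 ID, 24628 matched, giving 23115 genes; 718 genes had over 1 cluster and were represented by the cluster with the highest mean over the arrays of the arm. The platform table names 16098 clusters with 1 symbol, 0 with several, and does not list 37519; 14212 of 14310 names that could be compared were the same (99.3%). The 8988 clusters outside the workbooks were tested apart.

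Values were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with 1 fit per arm over all its groups, no covariates and Benjamini-Hochberg adjustment over genes; calls were at adjusted p under 0.05 and no gene was filtered. The comparisons were the inhibitor effect, the mimic effect in input, the difference of the pull-downs, their interaction with input (the specific enrichment), and pull-down against input for each mimic. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over 23 lists, and again with an estimated correlation. No list call was kept in that second test. Its p-values rose even where the estimate was below the preset value, so lost calls do not by themselves show correlation between members. For the RAS and MAPK pathway in the miR-340 pull-down, the estimate was 0.008 and the unadjusted camera p went from 0.0247 to 0.0511. The lists were the RAS and MAPK pathway, ERK transcripts, earlier miR-340 targets, microRNA machinery, pigment cell genes, the dedifferentiated melanoma state, DNA replication, mitosis, replication histones, ribosomal proteins, mitochondrially encoded transcripts, respiratory chain subunits, interferon-stimulated genes, NF-kappaB targets, the unfolded protein response, p53 targets, sterol synthesis, TGF-beta signalling, and markers of keratinocytes, fibroblasts, leukocytes and endothelial cells; a further list in the adjustment is not reported here. Overlaps of calls were tested with Fisher's exact test, two-sided. The groups, the tests of the comparisons, the lists, the rule for naming genes and the alternatives, except for 1 overlap selection, were chosen before the data were examined; tests of explanations chosen later are named as such where they are given. By that rule, genes named are the 8 largest rises and falls among called genes whose arrays do not overlap. Left out were pseudogenes, predicted loci and small RNAs of the microRNA, small nucleolar, small Cajal body, small nuclear, Y and vault classes. Other short RNAs such as RPPH1 were kept. Where none was called, the 5 smallest p in each direction are named. Up to 3 called members of a list are named too, as are fixed genes (those used here are MIR340, RNF130, MITF, MET, SKP2, RHOA and NRAS). Members of called lists that passed over the list alone, and others named beside them as values, were chosen after their values were seen, as was ACACB. The other carboxylase genes were chosen after the rise of ACACA and ACACB had been seen, but before their own values were.

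The procedure was tested on simulated data with the means of these arrays and 200 changed genes in each of 20 data sets per comparison. Noise was drawn independently for each gene, with the spreads as moderated by eBayes. The shares of changes recovered may therefore be too high for the real arrays. They also hold only for data with 200 changed genes, because Benjamini-Hochberg adjustment is stricter where fewer genes change. Of genes changed by 2-fold, 84.5% were recovered for the inhibitor effect, 94.9% for the mimic effect in input, 94.7% for the difference of the pull-downs, 59.3% for the interaction and 96.2% and 94.4% for pull-down against input with the miR-340 and the control mimic. Arrays shared by comparisons were treated by simulating unchanged mimics 50 times, with noise again independent between genes. No 2 arrays of a group held over 8 identical values. Alternatives were the workbook values, other normalizations, a filter on dim genes, other treatments of several clusters, an intensity trend, array weights, a replicate block, other thresholds and each array left out in turn. A planned test of seed matches in untranslated regions was not run, because no sequence was used here. Tables and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.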

Results

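Messenger RNA levels were measured on 18 one-colour gene arrays in 451 Lu, an established human melanoma cell line. Cells received a biotin-tagged mimic of miR-340, a microRNA, or a biotin-tagged mimic of the nematode microRNA cel-miR-67 as the control. From each mimic, total RNA (the input) and the RNA captured together with the tagged mimic (the pull-down) were hybridised, with 3 arrays in each of these 4 groups. In a second arm, cells received a vector expressing a miR-340 inhibitor or a non-targeting control hairpin, again with 3 arrays in each of 2 groups. Per the labels' protocols, cells of that arm that carried the vector's fluorescent marker were sorted 24 h after transfection. The labels call the arrays of a group biological replicates but do not describe separate cultures, so the p-values measure the spread between these arrays. Array medians lay between 4.59 and 4.69 on the log2 scale, and arrays of one group correlated across probe clusters with r from 0.987 to 0.994. The number of arrays limits the precision: the median standard error of a log2 difference between 2 groups was 0.142 in the mimic arm and 0.139 in the inhibitor arm. All p-values below for genes come from limma over 23115 named genes with Benjamini-Hochberg adjustment.

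The pull-down was set against its own input to ask which RNAs came down with each mimic. Among genes outside the small RNA, pseudogene and predicted classes, ACACA, which encodes the acetyl-CoA carboxylase of fatty acid synthesis, rose most with the miR-340 mimic. Its level was 10.58 ± 0.10 in the pull-down and 7.19 ± 0.13 in the input (log2, mean ± SD, n = 3 each), a difference of 3.39 ± 0.11 (SE; adjusted p = 3.09e-10). With the control mimic ACACA rose by 3.21 ± 0.11 (adjusted p = 6.53e-10). The proliferation marker MKI67 rose by 3.09 ± 0.12 and 3.23 ± 0.12, the kinetochore motor CENPE by 3.14 ± 0.18 and 3.26 ± 0.18, and the kinetochore protein CENPF by 2.84 ± 0.18 and 2.85 ± 0.18, with the miR-340 and the control mimic respectively. PVT1, a long non-coding RNA gene near MYC, rose by 2.99 ± 0.23 and 2.78 ± 0.23. The nuclear speckle protein gene SON rose by 2.92 ± 0.16 and 2.95 ± 0.16, the chromatin regulator ANKRD11 by 2.91 ± 0.13 and 2.88 ± 0.13, and the coiled-coil protein gene UACA by 2.86 ± 0.12 and 3.16 ± 0.12.

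Among the RNAs that were lower in the pull-down, the core histone gene H2BC3 fell by 2.60 ± 0.27 with the miR-340 mimic and by 2.38 ± 0.27 with the control mimic. COX8A, a subunit of cytochrome c oxidase, stood at 12.36 ± 0.02 in the miR-340 input and 10.29 ± 0.14 in its pull-down (SD, n = 3), and fell by 2.06 ± 0.13 and, with the control mimic, by 1.88 ± 0.13. The peroxiredoxin-like gene PRXL2C fell by 2.16 ± 0.15 and 1.93 ± 0.15, and the core histone genes H3C7 and H3C2 were at -2.03 ± 0.21 and -2.02 ± 0.32 with the miR-340 mimic and at -1.85 ± 0.21 and -2.33 ± 0.32 with the control mimic. With the miR-340 mimic the list of largest falls also held RIDA, a deaminase of reactive imines (-2.09 ± 0.12), RPPH1, the RNA part of RNase P (-2.03 ± 0.13), and MPC2, a subunit of the mitochondrial pyruvate carrier (-1.93 ± 0.15). With the control mimic it held the histone gene H2BC13 (-2.06 ± 0.26) and the long non-coding RNA genes STX17-DT (-2.06 ± 0.20) and GAPLINC (-1.86 ± 0.22). In all, 6920 genes differed with the miR-340 mimic, 2992 of them higher and 3928 lower, and 6695 with the control mimic, 2957 higher and 3738 lower. Beyond 2-fold, 857 genes were higher and 643 lower with the miR-340 mimic, against 872 and 587 with the control mimic.

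**Figure D1:**
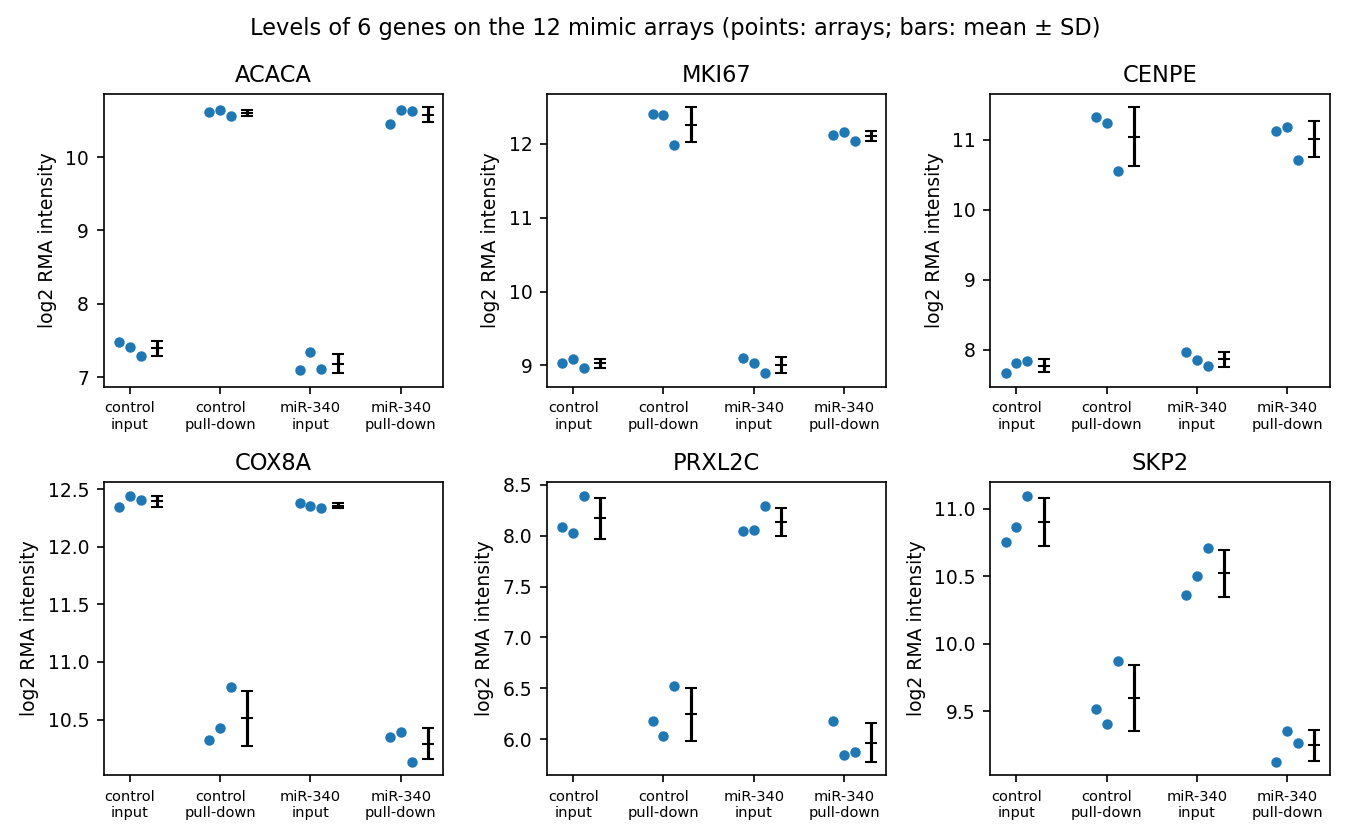
Levels of ACACA, MKI67, CENPE, COX8A, PRXL2C and SKP2 on the 12 mimic arrays, as log2 RMA intensity on axes that do not start at 0. Each point is an array, placed side by side in no order, bars give the mean ± SD of 3 arrays, and pull-down arrays lie above the input arrays of the same mimic for ACACA, MKI67 and CENPE and below them for the other genes.

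Genes of cell division went in 2 directions. Of 19 measured mitosis genes, 12 rose and 3 fell with the miR-340 mimic, and 12 rose and 2 fell with the control mimic; adjusted over the list alone, 12 rose and 4 fell with each. TOP2A, the topoisomerase that untangles chromosomes, rose by 2.03 ± 0.18 and 2.10 ± 0.18 beside CENPE and CENPF. The mean change of the list was 0.85 and 0.83 (camera adjusted p = 8.90e-06 and 1.52e-05; adjusted p = 0.214 and 0.227 with an estimated correlation). Of 20 genes of DNA replication, 2 rose and 12 fell with the miR-340 mimic and 2 rose and 13 fell with the control mimic, and adjusted over the list alone 3 rose and 14 fell with each. The helicase subunit MCM6 fell by 1.08 ± 0.11 and 0.98 ± 0.11, and the ribonucleotide reductase subunit RRM1 by 0.99 ± 0.12 and 0.97 ± 0.12. The list means were -0.44 and -0.39 (adjusted p = 0.00721 and 0.0187; adjusted p = 0.347 and 0.486 with an estimated correlation). Without replicate 3 of the control input, the call of this list with the control mimic was lost (adjusted p = 0.0625). Of 16 replication-dependent histone genes, 2 rose and 9 fell with the control mimic (2 and 11 adjusted over the list alone; mean -0.73, adjusted p = 0.00950, and adjusted p = 0.397 with an estimated correlation). Part of this mean rests on control pull-down replicate 1, whose list mean was 7.17 against 7.64 and 7.68 on the other control pull-down arrays. With the miR-340 mimic 1 rose and 8 fell, and the list did not pass (2 and 8 adjusted over the list alone; mean -0.65, adjusted p = 0.0563, and adjusted p = 0.347 with an estimated correlation). It passed with quantile normalization (adjusted p = 0.0297), without input replicate 2 (0.0302) or 3 (0.0449), and without pull-down replicate 1 (0.0420) or 3 (0.0478), so the mimics are not told apart by this list. The member that rose with both was H2BC7, by 2.44 ± 0.15 and 2.67 ± 0.15.

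Nuclear-encoded subunits of the respiratory chain were lower in both pull-downs. Of 18 measured members, 1 rose and 15 fell with each mimic, and adjusted over the list alone 2 rose and 15 fell with the miR-340 mimic and 1 rose and 15 fell with the control mimic. NDUFA9 of complex I fell by 1.37 ± 0.11 and 1.39 ± 0.11, and COX5A of complex IV by 1.38 ± 0.15 and 1.52 ± 0.15. The list mean was -0.69 and -0.66 (adjusted p = 7.46e-06 and 1.52e-05; adjusted p = 0.238 and 0.346 with an estimated correlation). The 17 sterol synthesis genes had means of -0.37 and -0.34, with 1 higher and 11 lower with the miR-340 mimic and 1 higher and 10 lower with the control mimic (adjusted p = 0.00876 and 0.0177; adjusted p = 0.347 and 0.438 with an estimated correlation; 1 and 11 adjusted over the list alone with each). The sterol oxidase MSMO1 fell by 1.56 ± 0.18 and 1.47 ± 0.18, and INSIG1, which retains the sterol sensor in the endoplasmic reticulum, by 0.95 ± 0.13 and 0.88 ± 0.13.

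Transcripts that follow ERK activity were higher on average. Of 20 measured, 8 rose and 3 fell with the miR-340 mimic and 9 rose and 3 fell with the control mimic; adjusted over the list alone these were 9 and 3, and 9 and 4. The receptor kinase gene EPHA2 rose by 1.60 ± 0.13 and 1.77 ± 0.13, and the immediate early transcription factor gene EGR1 by 1.47 ± 0.12 and 1.11 ± 0.12. The list mean was 0.36 and 0.35 (adjusted p = 0.00348 and 0.00253; adjusted p = 0.238 and 0.346 with an estimated correlation).

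The other lists did not pass with either mimic, though single members did. The RAS and MAPK pathway list of 23 genes had means of -0.23 and -0.19 (adjusted p = 0.0632 and 0.188). In it the RAS relative RRAS2 fell by 1.06 ± 0.15 and 0.86 ± 0.15, and the MEK gene MAP2K2 rose by 0.89 ± 0.15 and 0.76 ± 0.15. Pigment cell genes had means of -0.28 and -0.26 (adjusted p = 0.0816 and 0.168), with RAB27A, which moves melanosomes, at -1.27 ± 0.12 and -1.21 ± 0.12 and the ion exchanger of melanosomes SLC24A5 at -1.02 ± 0.11 and -1.04 ± 0.11. Genes of the dedifferentiated melanoma state had means of 0.25 and 0.16 (adjusted p = 0.0632 and 0.168), with a median of -0.03 for the control mimic, and the matrix protein gene TNC in it rose by 1.09 ± 0.13 and 0.99 ± 0.13. Ribosomal proteins had means of -0.25 and -0.21 (adjusted p = 0.0632 and 0.188). These 4 lists passed under some alternatives with the miR-340 mimic. With quantile normalization the RAS and MAPK pathway (adjusted p = 0.0182), pigment cell genes (0.0388) and ribosomal proteins (0.0310) passed. Without pull-down replicate 1 ribosomal proteins (0.0386) and the dedifferentiated state (0.0427) passed, the latter also without input replicate 2 (0.0324). With an estimated correlation the RAS and MAPK pathway and pigment cell genes were at 0.238, ribosomal proteins at 0.402 and the dedifferentiated state at 0.347. Interferon-stimulated genes had means of -0.21 and -0.19 (adjusted p = 0.257 and 0.395), with ISG15, a ubiquitin-like protein, at -1.79 ± 0.19 and -1.76 ± 0.19. For the microRNA machinery the means were 0.12 and 0.08 (adjusted p = 0.276 and 0.395), and the processing nuclease gene DROSHA rose by 1.05 ± 0.12 and 0.98 ± 0.12. For the unfolded protein response they were 0.07 and 0.09 (adjusted p = 0.812 and 0.711) with medians of -0.03 and -0.10, and PPP1R15A, which restores translation after stress, rose by 1.38 ± 0.12 and 1.41 ± 0.12.

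For genes that earlier work had put forward as miR-340 targets, the list mean was 0.01 and 0.02 (adjusted p = 0.812 and 0.737), with 5 higher and 5 lower of 15 with the miR-340 mimic and 3 higher and 3 lower with the control mimic. Adjusted over the list alone these were 5 and 7, and 4 and 4; the median with the control mimic was -0.01, and after quantile normalization the means relative to all genes were -0.04 and -0.03. The TGF-beta list had means of -0.28 and -0.21 (adjusted p = 0.173 and 0.373), p53 targets -0.25 and -0.18 (adjusted p = 0.173 and 0.395), and inflammatory NF-kappaB targets -0.10 with each (adjusted p = 0.812 and 0.827). Mitochondrially encoded transcripts had means of -0.10 and -0.01 (adjusted p = 0.812 and 0.921), and the test on the second of these pointed upwards against its mean. Markers of other cell types also did not pass: keratinocyte markers had means of 0.02 and -0.05 (adjusted p = 0.812 and 0.989), fibroblast markers -0.05 and -0.06 (0.984 and 0.951, with an upward test and a median of 0.02 for the first), leukocyte markers -0.12 and -0.14 (0.812 and 0.862) and endothelial markers 0.00 and 0.04 (0.812 and 0.716).

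Small nucleolar RNA genes were more often higher than lower in the pull-downs, and classes of RNA were not compared by a test. Of 188 measured, 89 rose and 12 fell with the miR-340 mimic and 88 rose and 14 fell with the control mimic, with median changes of 0.55 and 0.54, against -0.06 and -0.07 for 17322 protein-coding genes. Of the 23 small nuclear RNA genes, 5 rose and 8 fell, and 4 rose and 8 fell. Of 3757 long non-coding RNA genes, 186 rose and 308 fell with the miR-340 mimic and 161 rose and 320 fell with the control mimic. Among genes fixed for every comparison, SKP2, a ubiquitin ligase subunit that earlier work named as a miR-340 target, fell by 1.27 ± 0.15 and 1.30 ± 0.15. RNF130, the host gene of miR-340, fell by 0.63 ± 0.14 and 0.85 ± 0.14. NRAS fell by 0.57 ± 0.10 and 0.33 ± 0.10; the call with the control mimic was not kept throughout. It was lost with all arrays kept when only the arrays compared were fitted (-0.33, adjusted p = 0.0811) or with the pull-down and input of a mimic and number as a block (-0.33, adjusted p = 0.0516). The change was -0.39 to -0.26 with an array left out, and the call was also lost without control input replicate 1 (adjusted p = 0.0628), input replicate 3 (0.0873) or pull-down replicate 2 (0.113). MET (-0.43 ± 0.13, adjusted p = 0.0181) and RHOA (-0.69 ± 0.23, adjusted p = 0.0360) were called with the miR-340 mimic and not with the control mimic (-0.10 ± 0.13 and -0.60 ± 0.23). RHOA also passed with the control mimic under quantile normalization, with dim genes left out, an intensity trend, array weights or a replicate block (adjusted p = 0.0309 to 0.0441), and without control pull-down replicate 1 (-0.87, adjusted p = 0.00930). With an array left out, its change was -0.87 to -0.33 with the control mimic and -0.89 to -0.46 with the miR-340 mimic. The MET call was lost without miR-340 input replicate 1 (adjusted p = 0.0530) or 3 (0.0749) and without pull-down replicate 1 (0.0671) or 2 (0.0526). The RHOA call was lost without miR-340 input replicate 1 (0.0811), 2 (0.0704) or 3 (0.0674) and without pull-down replicate 2 (0.0674) or 3 (0.177). MITF and the precursor gene MIR340 were not called with either mimic.

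Pull-down and input differed in much the same way with both mimics. Genes called with both were 64.8% of the 8261 called with either. Of the 5354 genes called with both, 5351 moved the same way, and the changes correlated across genes with r = 0.905 (rho = 0.780; genes are not independent replicates). In common were 2467 higher genes, where independent lists would share 383, and 2884 lower genes, where they would share 635; the 2 comparisons share no arrays. The genes called in opposite directions, named after their values were seen, were the ubiquitin ligase gene WWP1 (-0.41 ± 0.10 with the miR-340 mimic and 0.38 ± 0.10 with the control mimic), LINC02212 (-0.40 ± 0.13 and 0.40 ± 0.13) and the predicted gene LOC100131395 (0.36 ± 0.12 and -0.41 ± 0.12). Calls with 1 mimic alone are not shown to differ between mimics, which the next comparisons tested.

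**Figure D2:**
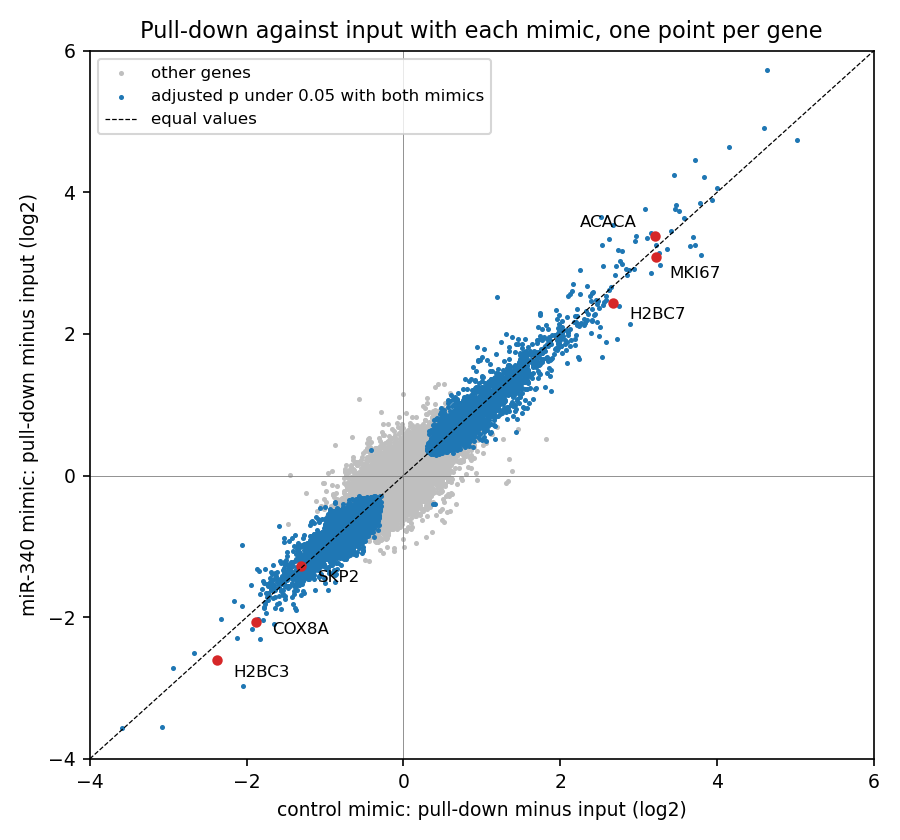
Pull-down minus input (log2) for each of 23115 genes, with the control mimic on the horizontal axis and the miR-340 mimic on the vertical axis. Blue points are the 5354 genes called with both mimics, grey points all other genes, red points 6 named genes, and the dashed line marks equal values; the points follow that line (r = 0.905).

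The pull-downs of the 2 mimics were then compared with each other, to ask which RNAs came down more with miR-340. No gene passed. The smallest p belonged to WWP1, at 8.47 ± 0.16 with the miR-340 mimic and 9.22 ± 0.06 with the control mimic (SD, n = 3 each), a difference of -0.74 ± 0.11 (SE; limma adjusted p = 0.131). PM20D2, a peptidase family gene, differed by -0.68 ± 0.13 and the transcriptional repressor gene ZNF703 by -0.54 ± 0.11 (adjusted p = 0.941 for both). The largest differences in the other direction by p were CARHSP1, an RNA-binding protein gene, at 0.58 ± 0.13, TMEM88 at 0.54 ± 0.12 and EGR1 at 0.46 ± 0.12 (adjusted p = 0.941, 0.941 and 1.00). SKP2 differed by -0.35 ± 0.15, NRAS by -0.27 ± 0.10, MET by -0.25 ± 0.13, MITF by 0.24 ± 0.13, RHOA by -0.17 ± 0.23, RNF130 by 0.13 ± 0.14 and MIR340 by 0.15 ± 0.18. With limma 0 genes had an adjusted p under 0.05, 1036 had an unadjusted p under 0.05 where chance gives 1156, and the authors' deposited table also held 0 clusters at that false discovery rate. With dim genes left out or with an intensity trend in the prior, WWP1 alone passed (adjusted p = 0.0381 and 0.00566; 0.00566 to 1 over its alternatives).

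No gene list passed in that comparison. The smallest adjusted p was 0.0728 for transcripts that follow ERK activity, with a mean of 0.09 and 15 of 20 members above 0; adjusted over the list alone, EGR1 rose (adjusted p = 0.0377). Earlier miR-340 targets had a mean of -0.11 and replication histones 0.17 (adjusted p = 0.0739 for both), and the remaining lists lay between 0.157 and 0.955. In the mean and the test, the lists that went different ways from their medians were respiratory chain subunits (mean -0.01, median 0.03) and p53 targets (mean -0.03, median 0.01). With the replicate number as a block, ERK transcripts, earlier miR-340 targets and replication histones passed (adjusted p = 0.0454 each), and with an estimated correlation they did not (adjusted p = 0.754, 0.564 and 0.754). The value for replication histones, relative to all genes, was 0.01 to 0.27 with an array left out and rested on control pull-down replicate 1, whose list mean was 7.17 against 7.64 to 7.69 on the other 5 pull-down arrays; without it the value was 0.01. For ERK transcripts the values were 0.05 to 0.13. Leaving out 1 array gave calls in 3 cases. Without control pull-down replicate 3, ERK transcripts and replication histones passed (adjusted p = 0.00900 for both); without control pull-down replicate 2, these passed (0.0376 and 0.0229) together with the dedifferentiated state (0.0376). Without miR-340 pull-down replicate 1, ERK transcripts passed (0.0450). With an estimated correlation and all arrays kept, the dedifferentiated state was also at 0.754.

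The enrichment with the miR-340 mimic over that with the control mimic was tested as an interaction. No gene passed. WWP1 had the smallest p again (-0.79 ± 0.15, limma adjusted p = 0.842), followed by LINC00333 (-0.75 ± 0.16), while among genes with positive values the antisense RNA gene CHRM3-AS1 reached 0.97 ± 0.20, the meiotic telomere protein gene MAJIN 0.83 ± 0.20 and PSTPIP1, an adaptor of the actin cytoskeleton, 0.86 ± 0.21 (adjusted p = 1.00 for each of these 4). MET had -0.32 ± 0.18, NRAS -0.24 ± 0.15, MITF 0.20 ± 0.18, RNF130 0.22 ± 0.19, MIR340 0.10 ± 0.25, RHOA -0.09 ± 0.33 and SKP2 0.03 ± 0.21. With limma 0 genes had an adjusted p under 0.05 and 938 an unadjusted p under 0.05 (456 positive and 482 negative), where chance gives 1156; the authors' deposited table also held 0 clusters. Of 23 gene lists 0 passed, with adjusted p from 0.818 to 0.870, and 0 members passed adjusted over the list alone. The mean and the median differed in sign for earlier miR-340 targets (-0.01 and 0.03), respiratory chain subunits (-0.03 and 0.01), NF-kappaB targets (-0.01 and 0.01) and fibroblast markers (0.01 and -0.04). In simulated data, 59.3% of genes changed by 2-fold were recovered in this contrast and 5.20% of those changed by 1.5-fold, shares that may be too high for the real arrays.

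In total RNA, the miR-340 mimic was compared with the control mimic to ask which transcripts the mimic lowered. No gene passed. LINC00333, a non-coding RNA gene near the floor of the array, differed by 0.71 ± 0.11 (2.36 ± 0.04 against 1.65 ± 0.18, SD, n = 3 each; limma adjusted p = 0.402). The ion channel family gene ANO2 differed by -0.74 ± 0.13 (adjusted p = 0.467), SLC24A4, an ion exchanger gene, by -0.56 ± 0.11 and the transcription factor gene ARNT2 by 0.48 ± 0.11 (adjusted p = 0.621 and 0.669). Of the fixed genes, SKP2 had the smallest p, at 10.52 ± 0.17 with miR-340 and 10.90 ± 0.18 with the control (-0.38 ± 0.15, adjusted p = 0.777). RNF130 was at -0.09 ± 0.14, NRAS at -0.03 ± 0.10, MITF at 0.03 ± 0.13, MET at 0.07 ± 0.13, RHOA at -0.08 ± 0.23 and MIR340 at 0.05 ± 0.18. The array's MIR340 cluster reads the precursor gene, with group means of 3.23 ± 0.43 and 3.18 ± 0.16 below the lower quartiles of the input arrays (3.42 to 3.47), and does not measure the mimic. With limma 0 genes had an adjusted p under 0.05, and 1303 had an unadjusted p under 0.05 (553 higher and 750 lower), where chance gives 1156; the authors' deposited table also held 0 clusters.

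Of 23 lists 0 passed in total RNA, with adjusted p from 0.245 to 0.977. The list of earlier miR-340 targets had a mean of -0.10 (adjusted p = 0.325), and adjusted over the list alone 2 of its 15 members fell, the kinase gene ROCK1 by 0.65 ± 0.20 and the stress response regulator NFE2L2 by 0.34 ± 0.10 (adjusted p = 0.0434 for both over the list alone, and 0.711 and 0.686 over all genes). In the microRNA machinery 1 of 12 members fell on the same terms, DICER1, the nuclease that cuts microRNA precursors (-0.35 ± 0.10, adjusted p = 0.0484 over the list alone and 0.686 over all genes). Transcripts that follow ERK activity had the smallest list p, with a mean of 0.09 (adjusted p = 0.245). The mean, the median or the test differed in sign for pigment cell genes (mean -0.02, median 0.01), genes of the dedifferentiated state (mean -0.01 with an upward test) and keratinocyte markers (mean -0.03, median 0.03). In simulated data, 94.9% of genes changed by 2-fold and 39.3% of those changed by 1.5-fold were recovered, shares that may be too high for the real arrays.

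The miR-340 inhibitor was compared with the control inhibitor to ask which transcripts rose when miR-340 was blocked. No single gene passed over all genes, while 2 gene lists did. Interferon-stimulated genes rose as a list, with a mean of 0.20, a median of 0.17 and 16 of 22 members above 0 (camera adjusted p = 0.0127; adjusted p = 0.774 with an estimated correlation). Adjusted over the list alone, 2 rose, both sensors of foreign RNA in the cytoplasm: IFIH1 by 0.65 ± 0.15 and RIGI by 0.59 ± 0.14 (adjusted p = 0.0483 for both over the list alone and 0.981 over all genes). IFIT2, an interferon-induced protein gene, was at 0.83 ± 0.23 and OAS2, a synthetase activated by foreign RNA, at -0.36 ± 0.14, and neither passed. The list mean of the arrays was 5.71, 5.45 and 5.65 with the control inhibitor and 5.94, 5.75 and 5.73 with the miR-340 inhibitor. Mitosis genes fell as a list, with a mean of -0.09 and a median of -0.11 and 3 of 19 members above 0 (adjusted p = 0.0316; adjusted p = 0.774 with an estimated correlation), and 0 members fell adjusted over the list alone. CENPE was at -0.19 ± 0.11, the checkpoint kinase gene TTK at -0.18 ± 0.11 and PLK1, another mitotic kinase gene, at -0.17 ± 0.10.

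Neither list call was kept with every array left out in turn. The interferon value, relative to all genes, was 0.13 to 0.27 and the mitosis value -0.11 to -0.05. The interferon call was lost without control inhibitor replicate 2 (adjusted p = 0.169) and without miR-340 inhibitor replicate 1 (0.290), and the mitosis call was lost without any one array other than control inhibitor replicate 1 (0.104 to 0.429). The mitosis call was also lost with the replicate number as a block (0.0581) and with arrays centred on their medians (0.0575), while the interferon call was kept with the block (0.00364). Among the other lists, the smallest adjusted p was 0.0648, for ERK transcripts with a mean of 0.09 (0.0218 without control inhibitor replicate 1, and 0.0413 with dim genes left out; 0.774 with an estimated correlation).

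Among single genes with the inhibitor, the lowest p belonged to the non-coding RNA gene RNPC3-DT (-0.98 ± 0.14; its other probe cluster gave -0.02), the adrenergic receptor gene ADRA2B (-0.72 ± 0.12) and the immune checkpoint receptor gene PDCD1 (-0.58 ± 0.11). Upwards they belonged to LINC02108 (0.83 ± 0.16), the bicarbonate transporter gene SLC4A5 (0.74 ± 0.14) and the lens crystallin gene CRYBA1 (0.73 ± 0.14), and the limma adjusted p was 0.981 for all 6. Of the fixed genes, MET was at -0.12 ± 0.20, RHOA at 0.09 ± 0.09, NRAS at -0.07 ± 0.10, RNF130 at 0.07 ± 0.10, SKP2 at -0.04 ± 0.10, MITF at -0.03 ± 0.11 and MIR340 at -0.09 ± 0.22. With limma 0 genes had an adjusted p under 0.05 and 1131 an unadjusted p under 0.05 (524 higher and 607 lower), where chance gives 1156; the authors' deposited table also held 0 clusters. The arrays of the 2 groups did not overlap for 9.80% of genes, where chance gives 10% for 3 against 3. In simulated data, 84.5% of genes changed by 2-fold and 14.7% of those changed by 1.5-fold were recovered. These shares may be too high for the real arrays, where RNPC3-DT did not pass at -0.98 ± 0.14.

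A direct target would be lower with the mimic, captured with it and higher with the inhibitor, so the comparisons were set against each other. At an adjusted p under 0.05 the overlaps held 0 genes, since the mimic and inhibitor comparisons called none with limma. The changes with the inhibitor correlated across genes with those in input RNA at r = 0.019 (rho = 0.021), with the pull-down difference at r = -0.007 (rho = -0.005) and with the specific enrichment at r = -0.019 (rho = -0.021). Input and pull-down differences between the mimics correlated at r = 0.045 (rho = 0.049). For input and specific enrichment, which share the input arrays, r was -0.720 (rho = -0.679) with a covariance of -0.0280, where unchanged groups simulated with the same shared arrays gave -0.707 (-0.714 to -0.700) and -0.0245 (-0.0251 to -0.0239). The observed values lay outside these ranges, as did the r of 0.045 between input and pull-down differences (-0.0115 to 0.0123). The simulated noise was independent between genes, which narrows the ranges, so values outside them do not show an effect of the mimic.

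The authors' deposited tables hold selections at an unadjusted p of at most 0.05 and at least 1.2-fold: 1421 clusters lower in miR-340 input, 922 more enriched with the miR-340 mimic and 1134 higher with the inhibitor. By the authors' deposited values, 23 clusters were in all 3 selections, where 12.2 would be if the inhibitor list were independent of the other two. Of these, 7 hold 1 named gene, CHST9, MIR517A, AMER3, SPTSSB, SMIM15-AS1, MARCHF11 and LHFPL3, named here after their values were seen. For CHST9, a carbohydrate sulfotransferase gene, the authors' deposited tables give signed folds of -1.30 in input, 1.57 in enrichment and 1.26 with the inhibitor, and for AMER3, of the family of APC membrane recruitment proteins, -1.45, 1.65 and 1.56. In the values fitted here, clusters lower in input and enriched overlapped those higher with the inhibitor at 1.89 times the number for independent lists, and those lower with it at 1.44 times (17 where 11.8 would be shared). Over the 18 other labellings of the inhibitor arrays the mean ratio was 1.35 and the highest 2.13. Over named genes the ratio was 1.99 for genes higher and 2.34 for genes lower with the inhibitor, and 0 of the 18 other labellings reached the first of these (mean 1.47, highest 1.94). The selections were made on these arrays and are not independent evidence.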

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

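The test of capture directed by the miR-340 mimic and all counts of other splits of the arrays, were chosen only after the results they concern had been seen; the tests of gene length and biotin carboxylases were set before the values they measure had been seen, though after the patterns they concern.

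Clusters that the deposited workbooks do not list were tested for the inhibitor apart from the named genes, and 3 of 8988 were higher with the miR-340 inhibitor than with the control inhibitor. They hold no gene name in the tables used here. Their differences were 4.18 ± 0.25, 3.13 ± 0.20 and 3.01 ± 0.23 (log2, SE, n = 3 each; limma adjusted p = 0.0171, 0.0171 and 0.0366 over these clusters, and 0.0198, 0.0198 and 0.0549 over all 53617). The first stood at 7.56 ± 0.32 with the miR-340 inhibitor and 3.38 ± 0.31 with the control inhibitor (SD), against group means of 2.78 to 3.15 in the mimic arm. In the same clusters 0 passed with limma in the comparisons between mimics (542, 269 and 374 at an unadjusted p under 0.05 for input, pull-down and specific enrichment).

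Pull-down and input differed in much the same way with both mimics: 2467 genes were called higher and 2884 lower with both, and the genes called with both were 64.8% of those called with either. The control mimic carries another microRNA and gave changes that correlated with those of miR-340 at r = 0.905, which argues against capture directed by miR-340 as the source of the shared differences. The SD of the specific enrichment over genes, 0.227, was 1.03 times its mean in unchanged simulated data (highest 0.223); it follows from that agreement, is no further evidence, and leaves a small directed part open. Enrichment correlated only weakly with genomic length across genes, at rho = 0.07 (0.08 with the control mimic; 0.12 and 0.13 over protein-coding genes), which argues against genomic length as the main source; transcript length was not tested. RNA that binds the beads, the tag or any loaded small RNA may be the source, as may features of a transcript, its length included; these were not tested, because no capture without a mimic was used here.

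ACACA and ACACB encode enzymes that carry biotin, and both rose in both pull-downs, ACACB by 2.20 ± 0.10 with the miR-340 mimic and 2.35 ± 0.10 with the control mimic. A candidate explanation is that the beads held biotin-carrying protein together with the mRNA being translated. Of PC, PCCA and MCCC1, the other genes of carboxylases that carry biotin, 0 were called higher with limma in both pull-downs: PC was at -0.02 ± 0.11 and -0.01 ± 0.11, PCCA at -0.26 ± 0.12 and 0.01 ± 0.12, and MCCC1 at -0.76 ± 0.13 and -0.91 ± 0.13. This argues against capture of every biotin-carrying protein with its mRNA. PC, PCCA and MCCC1 act in mitochondria and ACACA and ACACB do not, and whether the biotin of these enzymes is added at a different time was not tested.

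For pull-down against input, 3 against 3 arrays make too few splits for a share under 0.05. The real split, 1 of 10, called 6920 genes with the miR-340 mimic and 6695 with the control mimic, and the highest of the others called 0 with each. Every other split mixes pull-down and input arrays within each group. The difference between these fractions then enters the spread, so few or no calls could arise, and the 0 says nothing on chance. For comparisons between groups of 3 the splits are again too few: for the inhibitor 1131 genes had an unadjusted p under 0.05 and 7 of 10 splits, counting the real one, gave as many (highest other 1619). For the mimics in input RNA these were 1303 genes, 8 of 10 and 1886, and for the pull-downs 1036 genes, 4 of 10 and 1318. For specific enrichment 938 genes had an unadjusted p under 0.05, and 86 of 100 relabellings gave as many (highest other 1915), so chance is not excluded.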

How the results depend on the processing

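The overlap of genes at an unadjusted p of at most 0.05 and at least 1.2-fold was chosen only after the data had been seen; the other alternatives here were not. At that selection the 5 overlaps that held 0 genes at adjusted p under 0.05 held 19 (lower in input, higher with the inhibitor), 10 (higher in the pull-down and with the inhibitor), 19 (enriched and higher with the inhibitor), 15 (lower in input, higher in the pull-down) and 236 genes (lower in input and enriched). The alternatives fixed beforehand for seed sites (untranslated regions, site definition and microRNA arm) were not run, since no sequence was used here. Low signal limits genes near the floor: the group means of MIR340 lay below the lower quartiles of the arrays.

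Among main results, 239 values stayed and 13 moved with an array left out, and 237 stayed and 19 moved under the other settings. For the named genes reported here 1340 values stayed, 1 passed newly, 42 no longer passed and 27 changed sign with an array left out; under other settings these were 2246, 8, 14 and 5. For the lists reported here 807 results stayed, 14 passed newly, 8 no longer passed and 95 changed the direction of the test with an array left out, against 605, 8, 15 and 21 under other settings. The cause was not tested unless stated.

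With the replicate number as a block, 6800 and 6596 genes were called for the miR-340 and the control pull-down, and 6615 and 6437 with the pull-down and input of a mimic and number as a block; the 4 comparisons between mimics or inhibitors had 0 with limma, as without the block. With that block 1 list was called for the inhibitor (interferon, adjusted p = 0.00364; mitosis 0.0581) and 3 for the difference of the pull-downs (ERK transcripts, earlier targets and replication histones, 0.0454 each). By their residuals, replicate numbers did not pair the arrays of the mimic arm. In the inhibitor arm each array matched best the array of its own number, but only at r = 0.05, 0.06 and 0.02 across genes. Same-number values in the mimic arm were of similar size, at 0.05, -0.02 and 0.06 for control input with control pull-down. Pairing is therefore not shown in either arm.

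At 1.5-fold or more, 4219 and 4072 genes were called with the miR-340 and the control mimic, and 1643 lower genes were in common; this threshold removes genes by construction. In the difference of the pull-downs 1 gene, WWP1, passed with dim genes left out (fewer genes tested) and 1, WWP1, with an intensity trend. Leaving out each array gave 0 to 1 there; the gene, without control pull-down replicate 3, was TMEM160 (-1.83 ± 0.20, limma adjusted p = 0.0134), chosen after its values were seen. With an estimated correlation 0 lists were called for the inhibitor, 0 for the miR-340 pull-down and 0 for the control pull-down. With arrays centred on their medians 1 list was called for the inhibitor, and with quantile normalization 9 were for the miR-340 pull-down. With an array left out, the number of lists was 0 to 3 for the inhibitor, 0 to 3 for the difference of the pull-downs and 5 to 8 for the miR-340 pull-down. With dim genes left out the correlations of fold changes were 0.079 (input with pull-down difference) and 0.944 (both pull-downs), and with an array left out the second was 0.887 to 0.900.

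Single genes whose change took the other sign under a setting were few. With array weights, for the difference of the pull-downs, the value was 0.04 (RHOA). In that setting, for specific enrichment, the value was 0.13 (RHOA). With quantile normalization, for the miR-340 pull-down, the value was 0.05 (MIR340). Likewise for the control pull-down, the value was -0.09 (MITF). With the mean of the clusters of a gene, for the control pull-down, the value was 0.01 (SMAD4). For SMAD4 this follows from its other clusters, at 1.03 and -0.12 beside the -0.87 used. With an array left out, the lowest and highest log2 changes were these where the sign changed. For the inhibitor they were -0.27 to 0.09 (MET), -0.24 to 0.15 (MIR340) and -0.06 to 0.03 (MITF). For the mimics in input they were -0.04 to 0.15 (MET), -0.07 to 0.00 (NRAS), -0.18 to 0.25 (MIR340) and -0.04 to 0.12 (MITF). For the difference of the pull-downs they were -0.04 to 0.25 (RNF130) and -0.44 to 0.09 (RHOA). For specific enrichment they were -0.10 to 0.33 (MIR340), -0.36 to 0.18 (RHOA) and -0.07 to 0.17 (SKP2). For the miR-340 pull-down they were -0.23 to 0.20 (MIR340). For the control pull-down they were -0.10 to 0.13 (MITF). Of genes called with the miR-340 pull-down, COX1, DSG3, LUM, MET, ND1, ND5, RHOA, RPL30 and SMAD4 were lost under at least 1 alternative, and of those called with the control pull-down, BIRC3, COX1, NRAS, RPS23 and SMAD4.

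Lists for which the camera test took the other direction did not pass under these settings. Values are the list mean minus the mean of all genes, which did not always change sign with the test. With the replicate block, for the mimics in input, the value was 0.00 (sterol synthesis). With dim genes left out, for the inhibitor, the value was 0.03 (dedifferentiated state). With the same choice, for the mimics in input, values were 0.01 (microRNA machinery), -0.01 (dedifferentiated state) and 0.00 (sterol synthesis). Under the same setting, for the difference of the pull-downs, values were 0.00 (fibroblast) and 0.01 (endothelial). In that setting, for the miR-340 pull-down, values were -0.02 (NF-kappaB), -0.06 (fibroblast) and -0.01 (endothelial). Likewise for the control pull-down, the value was -0.02 (NF-kappaB). With quantile normalization, for the mimics in input, values were 0.00 (microRNA machinery), -0.01 (sterol synthesis) and 0.03 (TGF-beta). With the same choice, for the difference of the pull-downs, the value was 0.00 (fibroblast). Under the same setting, for the miR-340 pull-down, the value was -0.04 (earlier miR-340 targets). In that setting, for the control pull-down, values were -0.03 (earlier miR-340 targets), 0.02 (keratinocyte), 0.00 (fibroblast) and -0.06 (leukocyte). With arrays centred on their medians, for the difference of the pull-downs, the value was 0.00 (fibroblast).

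With an array left out, the same list values had these lowest and highest values where the direction of the camera test changed. For the inhibitor they were 0.00 to 0.03 (RAS and MAPK), -0.03 to 0.01 (dedifferentiated state), -0.05 to 0.01 (DNA replication), -0.09 to 0.02 (replication histones), 0.00 to 0.03 (ribosomal proteins) and 0.01 to 0.09 (NF-kappaB). Also for the inhibitor they were -0.04 to 0.03 (keratinocyte) and -0.05 to 0.04 (leukocyte). For the mimics in input they were 0.00 to 0.04 (RAS and MAPK), -0.02 to 0.03 (microRNA machinery), -0.03 to 0.00 (pigment cell genes), -0.04 to 0.05 (dedifferentiated state), -0.04 to 0.15 (mitochondrially encoded) and 0.00 to 0.06 (respiratory chain). Also for the mimics in input they were -0.04 to 0.03 (interferon), -0.02 to 0.13 (unfolded protein response), -0.02 to 0.04 (sterol synthesis), -0.03 to 0.09 (TGF-beta) and -0.03 to -0.01 (keratinocyte). Also for the mimics in input they were -0.06 to 0.02 (fibroblast) and -0.02 to 0.09 (endothelial). For the difference of the pull-downs they were -0.03 to 0.07 (DNA replication), -0.01 to 0.08 (mitosis), -0.02 to 0.06 (ribosomal proteins), -0.12 to 0.07 (mitochondrially encoded), -0.07 to 0.06 (respiratory chain) and -0.02 to 0.09 (unfolded protein response). Also for the difference of the pull-downs they were -0.06 to 0.05 (sterol synthesis), -0.02 to 0.02 (fibroblast) and -0.07 to 0.04 (endothelial). For specific enrichment they were -0.04 to 0.04 (ERK transcripts), -0.05 to 0.00 (earlier miR-340 targets), -0.04 to 0.00 (pigment cell genes), -0.10 to 0.01 (DNA replication), -0.04 to 0.05 (mitosis) and -0.08 to 0.18 (replication histones). Also for specific enrichment they were -0.08 to 0.01 (ribosomal proteins), -0.19 to 0.01 (mitochondrially encoded), -0.10 to 0.03 (respiratory chain), -0.05 to 0.01 (NF-kappaB), -0.11 to 0.05 (unfolded protein response) and -0.07 to 0.05 (sterol synthesis). Also for specific enrichment they were -0.13 to -0.01 (TGF-beta), -0.03 to 0.05 (fibroblast), -0.03 to 0.04 (leukocyte) and -0.11 to 0.01 (endothelial). For the miR-340 pull-down they were -0.15 to 0.04 (mitochondrially encoded), -0.06 to 0.01 (fibroblast) and -0.03 to 0.08 (endothelial). For the control pull-down they were -0.06 to 0.12 (mitochondrially encoded), -0.03 to 0.01 (keratinocyte) and -0.07 to 0.00 (fibroblast).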

Other observations

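The test of input arrays shared by both comparisons was chosen only after its result was seen, as was the selection at an unadjusted p of at most 0.05 and at least 1.2-fold on which all overlaps here rest; the tests on variable genes and on regulation by miR-340 were not.

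Genes more enriched with the miR-340 mimic than with the control mimic overlapped genes higher with the inhibitor: 19 genes were in both, where independent lists of 456 and 493 would share 9.73 (two-sided Fisher's exact p = 0.00757, adjusted p = 0.0132 over 7 overlaps at this selection). Regulation by miR-340 would favour genes higher with the inhibitor. Yet genes lower with it overlapped by 22 where 11.5 would be shared (two-sided Fisher's exact p = 0.0038, unadjusted), a ratio of 1.91 against 1.95. Fisher's test takes genes as independent, which they are not. Variable genes that enter both lists could raise both overlaps. Over the 18 other labellings of the inhibitor arrays the mean ratio was 1.36 and the highest 1.98, between the bounds set for that test, so neither explanation is settled. The overlaps rest on genes of which 0 pass with limma in either comparison (938 and 1131 at an unadjusted p under 0.05).

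Among probe clusters, 479 were both lower in miR-340 input and more enriched, where independent lists would share 29.4. Both comparisons use the same input arrays. Unchanged groups simulated with these shared arrays gave 408.6 on average (363 to 449), so in simulation the shared arrays alone gave most of this number. Over named genes the overlap was 236 against 205.2 (167 to 247). The simulated noise was independent between genes, which narrows these ranges, so the excess of clusters does not show an effect of the mimic. The enriched list was smaller than simulated (456 genes against 575.5, and 922 clusters against 1113) and the list lower in input was larger (719 genes against 548.4, and 1421 clusters against 1107). The overlap was therefore a larger part of the first list than simulated, at 51.8% against 35.6% for genes, and not of the second. Genes lower in input and higher with the inhibitor numbered 19 against 15.3 for independent lists (adjusted p = 0.499), those higher in the miR-340 pull-down and with the inhibitor 10 against 8.47 (0.596), and those lower in input and higher in the pull-down 15 against 12.3 (0.540).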
